A study of Mus musculus with 27 samples.

How the data were processed

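Small RNA libraries were made from cortex of wild-type C57BL6 mice, a common inbred laboratory strain, after sham surgery or after middle cerebral artery occlusion (MCAO), a model of ischemic stroke in which a suture blocks the artery that supplies most of the lateral cortex. Per the labels' protocols the occlusion lasted 35 min, and tissue was taken 3, 6, 12 or 24 h into recovery from the occluded (ipsilateral) or the opposite (contralateral) hemisphere. RNA was extracted with Trizol, libraries followed the TruSeq small RNA protocol with inserts of 15 to 35 bp, and reads were 69 bp single-end from a MiSeq, per the labels' protocols. The 27 libraries form 9 groups of 3: sham, and contralateral and ipsilateral cortex at each of 4 times, written below as contra_3h, ipsi_3h and so on.

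The authors deposited 1 table of raw counts of 1842 mature miRNA entries in the 27 libraries, with whole numbers whose totals differ between libraries. Novoalign and edgeR are named in the submitters' processing notes, without a role or a version. The genome build, the miRNA annotation release and the treatment of reads that match several entries are not given in the sources used here. Members of one family with nearly identical sequences, such as the let-7, miR-29, miR-30 and miR-181 families, can share reads, so values of single members are uncertain to that extent. The table holds no sequences and no coordinates. All of its 27 columns were used.

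Total counts ranged from 856591 to 1903416 per library, and the median count of an entry within a library was between 6 and 29. Levels are given in CPM, the counts scaled by the library total times its TMM factor, unless a value is said to be CPM of the total alone. Intervals of shares are 95% Wilson intervals. They cover counting error only, since reads amplified by PCR carry no molecular identifiers here.

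The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM factors and robust dispersions. One model with a mean per group was fitted to all 27 libraries, leaving 18 residual degrees of freedom. The filterByExpr filter kept 1470 entries, which hold 99.9% of the counts, and removed 372. P-values were adjusted by the Benjamini-Hochberg method over the entries tested, and an adjusted p under 0.05 was a call. The 12 pairwise comparisons were ipsilateral against contralateral, ipsilateral against sham and contralateral against sham at each time. A joint F test asked whether the hemispheres differed at any time, and another whether that difference changed over time. Before the data were examined, 21 lists of miRNAs were fixed, among them families, genomic clusters and markers of other cell types that cortex samples can hold. Of their 174 members, 167 were in the table and 158 were tested. The 20 lists with at least 2 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. In DESeq2 a local regression replaced the parametric dispersion trend where that trend captured the data poorly. The muscle list had 1 tested member.

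The rule for naming miRNAs was also fixed before the data were examined. It takes up to 12 calls per direction by the size of the fold change in each ipsilateral against contralateral comparison, with a mean of at least 10 CPM, and up to 6 per direction in each comparison with sham. It adds up to 12 calls of the test of change over time, any detected list member, and the 10 miRNAs of highest mean level. Entries named outside it are marked as chosen after their values were seen.

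The series' design text states that replicates come from different days of surgery, and the replicate number was taken to pair libraries by day. Where surgery days are named below, they are replicate numbers. Whether the ipsilateral and contralateral libraries of one number come from the same animal is not given in the sources used here, so the block stands for the day of surgery. Deviations from the group means correlated at a mean of 0.23 over the 108 pairs of libraries from different groups with the same number, and at -0.12 over the 216 pairs with different numbers. The negative value follows from subtracting the group means once the first is positive, so it is not separate evidence for the pairing. The first principal component held 41.4% and the second 11.8% of the variance. A fit with the replicate number as a block is given beside a result where it ends a call or moves a count by over 1.5 times. Calls that only this fit makes are named for some entries and otherwise given as a count. No 2 libraries of a group agreed within sampling noise: the smallest chi-square per degree of freedom between replicates was 11.2.

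On simulated counts with the means and library sizes of these data, the test of ipsilateral against contralateral cortex at 24 h over 1470 entries recovered 23% of 100 entries changed 2-fold and 76% of 100 changed 4-fold, with 5 false calls. For the test of change over time the shares were 6% and 38%, also with 5 false calls. The simulation held no effect of the surgery day, used the same dispersion of an entry in all groups, and balanced rises and falls. The shares and false calls need not hold where the data differ from that.

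The alternatives were RLE factors, total counts without TMM, no filter, DESeq2 1.42.0, the replicate block, thinning to the smallest library, leaving out each library, fitting only the 6 libraries compared, and for lists the other correlation and fry. After the data were seen, TMM factors from the 286 tested miRNAs with a mean of at least 100 CPM and a fit without 2 libraries of high miR-182-5p were added, as was camera among those 286 miRNAs alone. For a check of GC content and for positions, entries were matched by name to hairpins in GENCODE M21 (GRCm38), which gave 1804 of 1842 entries a hairpin. Whether these are the positions the authors used is not known.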

Results

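The data are miRNA counts from mouse cortex over the first day after a transient stroke. Each of the 9 groups has 3 libraries: sham cortex, and contralateral and ipsilateral cortex at 3, 6, 12 and 24 h after MCAO. Total counts per library ranged from 856591 to 1903416. The most abundant miRNA was miR-181a-5p with 99131 ± 14999 CPM of the library totals (SD over 27 libraries), followed by miR-128-3p with 76571, miR-127-3p with 76377, miR-26a-5p with 72981 and let-7f-5p with 61750 CPM. Next came miR-22-3p with 61557, miR-434-3p with 36034, miR-9-5p with 30408, miR-30a-5p with 24704 and miR-27b-3p with 20986 CPM. These 10 miRNAs took 56.2% ± 1.22 of the counts in sham (SD, n = 3) and 52.1% ± 4.67 in ipsi_24h.

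The comparison of the hemispheres asks which miRNAs differ in the occluded cortex at each time. At 3 h and at 6 h no miRNA passed the edgeR test. The rule names miR-3960 and miR-701-5p for later times only, so their values at 3 h and 6 h were chosen after they were seen. At 3 h miR-3960 was at 478 ± 193 CPM in ipsilateral and 75.9 ± 25.3 CPM in contralateral cortex (SD, n = 3 each). Its log2 fold change was 2.65 ± 0.67 (SE) with an edgeR adjusted p of 0.18, where the smallest of any entry was 0.069. At 6 h miR-701-5p was at 168 ± 141 against 12.4 ± 2.83 CPM, a log2 fold change of 3.75 ± 0.77 with an edgeR adjusted p of 0.076. miR-210-3p, a hypoxia-induced miRNA, had log2 fold changes of -0.50 ± 0.34 at 3 h and -0.36 ± 0.34 at 6 h (edgeR adjusted p = 0.999 and 0.987). An unadjusted p under 0.05 was reached by 58 of 1470 entries at 3 h and 64 at 6 h, where 73.5 would be expected by chance. The main fit leaves out the replicate number, and its common dispersion was 0.123, against 0.082 with the block. Counts under 73.5 therefore do not show that the hemispheres are equal. DESeq2 called 11 entries at 3 h and 4 at 6 h, all higher in ipsilateral cortex, and gave no adjusted p for 915 entries at 3 h. Without ipsi_3h replicate 2 edgeR called 2 entries at 3 h, and without ipsi_6h replicate 1 it called 1 at 6 h.

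Among the lists, none passed at 3 h and 5 passed at 6 h, with no single member called. The 6 tested members of the miR-200 and miR-183 clusters, which mark epithelial and sensory tissue, had a median log2 fold change of 3.30 at 6 h (camera adjusted p = 0.0096, and adjusted p = 0.58 with an estimated correlation). All 6 were called when adjusted over the list alone. These values came with 1 library, ipsi_6h replicate 3, in which miR-182-5p held 20875 CPM of the total (95% Wilson interval 20617 to 21136), against 227 and 101 CPM in the other ipsi_6h replicates. The other 4 lists were directed down: the vascular list with a median of -0.48 (camera adjusted p = 0.035), the erythrocyte list with -0.36 (0.035), the Dlk1-Dio3 imprinted cluster with -0.16 (0.029) and the miR-23/27/24 clusters with -0.30 (0.046). With an estimated correlation their adjusted p values were 0.58, 0.39, 0.59 and 0.58. Without ipsi_6h replicate 3 the number of lists was 2, without contra_6h replicate 2 or ipsi_6h replicate 1 it was 1, and without contra_6h replicate 3 it was 2. Without contra_6h replicate 1 it was 10 and without ipsi_6h replicate 2 it was 9. With the replicate block 3 lists passed at 3 h and 9 at 6 h. At 3 h these were the choroid plexus list (adjusted p = 0.023, directed up), the neuron-enriched list (0.046) and the miR-15/16 family (0.046), and without the block each had an adjusted p = 0.83 with an estimated correlation. At 6 h the added lists were the miR-29 family, the neuron-enriched list, the miR-15/16 family (0.014 each) and the miR-30 family (0.025). With an estimated correlation and no block their adjusted p values were 0.58, 0.59, 0.58 and 0.58. Leaving out contra_3h replicate 1, ipsi_3h replicate 2 or ipsi_3h replicate 3 gave 8, 6 and 2 lists at 3 h.

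At 12 h, 64 miRNAs were higher in ipsilateral than in contralateral cortex and none was lower (edgeR), and with the replicate block 54 were higher and 1 lower. The rise was led by miR-701-5p, which went from 13.6 ± 5.89 to 1548 ± 1835 CPM (SD, n = 3), a log2 fold change of 6.82 ± 0.86 (SE, edgeR adjusted p = 3.7e-05). After it came miR-7687-3p with 5.65 ± 0.95, miR-6240 with 5.15 ± 0.83, miR-6968-5p with 5.13 ± 0.78, miR-718 with 5.04 ± 0.80 and miR-1893 with 4.96 ± 0.85 (edgeR adjusted p between 5.3e-04 and 8.9e-04). The other named entries, miR-2861, miR-3109-5p, miR-1934-5p, miR-7034-3p, miR-346-3p and miR-6538, had log2 fold changes between 4.70 and 3.98. Most called entries were rare in contralateral cortex, with a median of 10.4 CPM, and 40 of the 64 had means under 100 CPM over all libraries. Members of the fixed lists were called in 2 cases. miR-494-3p of the Dlk1-Dio3 cluster had a log2 fold change of 3.40 ± 0.71 (edgeR adjusted p = 0.0050). miR-18a-5p of the miR-17/92 cluster, known for its part in cell proliferation, had 3.33 ± 0.90 (adjusted p = 0.029), which did not pass with the replicate block (adjusted p = 0.14). The other 11 tested miR-17/92 members and the other 47 of the Dlk1-Dio3 cluster were not called. No list passed camera at 12 h, and without contra_12h replicate 1 or ipsi_12h replicate 2 the numbers of lists were 1 and 2.

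The 12 h count rests on single libraries. In ipsi_12h replicate 3 miR-6240 stood at 2986 CPM, against 228 and 166 CPM in replicates 1 and 2, and the count was 10 without that library and 104 without ipsi_12h replicate 2. The groups of 3 libraries did not overlap for 128 of the 1470 entries (8.71%), against 10% by chance. Entries called lower, 0 in the test of all libraries, numbered 1 without contra_12h replicate 1 or 2 or ipsi_12h replicate 1, and 2 without ipsi_12h replicate 2. The count of all calls was 34, 28 and 24 without contra_12h replicates 1, 2 and 3, 39 with TMM factors from abundant miRNAs and 0 when only the 6 libraries were fitted. Without ipsi_12h replicate 3 the edgeR adjusted p was 0.33 for miR-494-3p, 0.998 for miR-18a-5p, 0.25 for miR-7034-3p, 0.096 for miR-346-3p and 0.084 for miR-6538. For miR-18a-5p it was 0.11, 0.12 and 0.15 without contra_12h replicates 1, 2 and 3.

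At 24 h, 174 miRNAs were higher and 21 lower in ipsilateral cortex (edgeR). miR-701-5p was at 6261 ± 5631 CPM against 21.8 ± 8.45 CPM in contralateral cortex (SD, n = 3), a log2 fold change of 8.17 ± 0.89 (SE, edgeR adjusted p = 2.6e-06). In sham cortex it was at 18.1 ± 4.72 CPM. miR-7687-3p had a log2 fold change of 6.76 ± 0.98, miR-6968-5p of 6.66 ± 0.82, miR-1893 of 6.36 ± 0.90, miR-718 of 6.23 ± 0.84 and miR-3109-5p of 6.01 ± 0.84. miR-6240 reached 2709 ± 1601 CPM from 51.6 ± 26.1 CPM, and miR-3960 2906 ± 2572 CPM from 69.1 ± 25.6 CPM. The further named entries miR-2861, miR-5131, miR-1892 and miR-8109 had log2 fold changes between 5.51 and 5.31. All 64 entries called at 12 h were also among the 174 at 24 h, where 7.58 would be shared by independent lists. The 2 groups of 3 libraries did not overlap for 415 of the 1470 entries (28.2%), against 10% by chance and against 133 (9.05%) at 3 h and 157 (10.7%) at 6 h. Without ipsi_24h replicate 1 the calls were 104 higher and 3 lower.

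The hairpin of miR-701-5p, matched by name, lies at chromosome 5, 111004144 to 111004252, plus strand, in an intron of Ttc28 (GRCm38). That of miR-6968-5p lies at chromosome 17, 26935472 to 26935539, in an intron of Phf1 and over an exon of Cuta on the other strand. miR-2861 and miR-3960 lie next to each other in an exon of Cdk9, at chromosome 2, 32712807 to 32712888 and 32712900 to 32712972. miR-1893 lies in an exon of Epc1 at chromosome 18, 6490564 to 6490646. The miR-6240 hairpin is at chromosome 5, 114851948 to 114852064, outside any other gene on its strand. The hairpins of the entries called higher had a median GC content of 59.0% (169 with a hairpin), against 52.1% for the other tested entries.

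**Figure D1:**
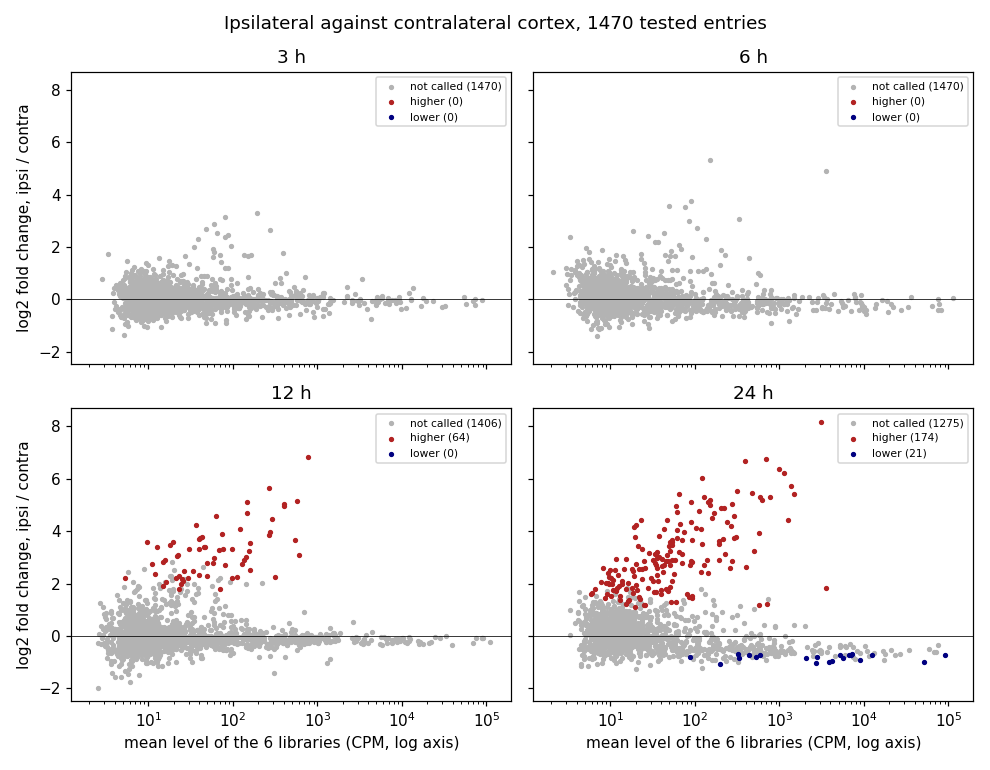
Log2 fold change of ipsilateral over contralateral cortex (vertical axis) against mean level in CPM on a log axis, for 1470 entries at each time. Red points are called higher and blue points lower by edgeR: none at 3 and 6 h, 64 higher at 12 h, and 174 higher and 21 lower at 24 h, where most abundant entries sit below 0 under the TMM scaling plotted (their median under total counts was 0.03).

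**Figure D2:**
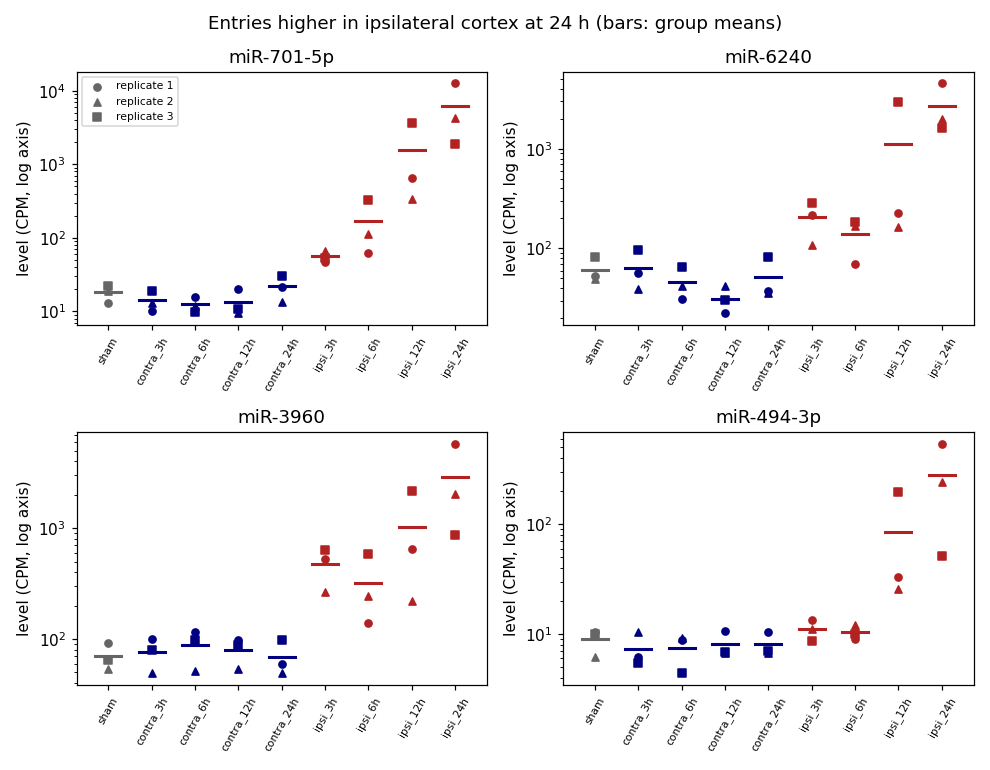
Levels in CPM on a log axis of miR-701-5p, miR-6240, miR-3960 and miR-494-3p in each library, by group, with bars at the group means and marker shapes for the replicate. The libraries ipsi_12h replicate 3 and ipsi_24h replicate 1 hold the highest values of miR-701-5p in their groups, with 3659 and 12613 CPM.

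The 21 lower miRNAs at 24 h were mostly abundant ones: 20 had means of at least 100 CPM. let-7f-5p, of a family that marks differentiated cells, was at 34113 ± 9341 CPM in ipsilateral and 67689 ± 12692 CPM in contralateral cortex (SD, n = 3), a log2 fold change of -0.99 ± 0.24 (SE, edgeR adjusted p = 0.0049). miR-1843a-3p had -1.08 ± 0.30, miR-328-3p -1.02 ± 0.27, miR-222-3p -0.98 ± 0.29, let-7d-5p -0.94 ± 0.23 and miR-30c-5p -0.90 ± 0.29. let-7e-5p, let-7j, miR-351-5p, miR-423-5p, miR-342-5p and miR-744-5p had log2 fold changes from -0.85 to -0.80. These values depend on the scaling. Under TMM the median log2 fold change of all tested entries was 0.08 and that of the 286 abundant miRNAs -0.46. Under total counts the medians were 0.57 and 0.03, and the calls were 226 higher and 0 lower. With the replicate block the calls were 198 higher and 96 lower, and without ipsi_24h replicate 1 there were 107 in all. The 21 lower calls became 3 without that library, 4 without contra_24h replicate 1 and 11 without contra_24h replicate 2, and DESeq2 called 42 lower. Without ipsi_24h replicate 1 the calls of 11 of the 12 named lower miRNAs were lost (edgeR adjusted p from 0.052 for miR-423-5p to 0.255 for miR-30c-5p, and 0.077 for let-7f-5p). That of let-7d-5p was lost without contra_24h replicate 1 (0.061). Each of the other libraries of the comparison, contra_24h replicates 2 and 3 and ipsi_24h replicates 2 and 3, also ended some of these calls, as for miR-222-3p (0.10), miR-342-5p (0.071), miR-351-5p (0.081) and let-7j (0.071) in that order.

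Of the 20 lists tested at 24 h, 4 passed, all directed down relative to the other entries. In the let-7 family 6 of 9 members fell and 3 were not called, with a median log2 fold change of -0.74 (camera adjusted p = 1.3e-05, and adjusted p = 0.55 with an estimated correlation), and 8 were called when adjusted over the list alone. Without contra_24h replicate 1 the 6 became 1, let-7f-5p, and without ipsi_24h replicate 1 they became 1, let-7d-5p (edgeR adjusted p of the lost calls from 0.0525 to 0.265). In the miR-181 family 3 of 4 fell, with a median of -0.71 (adjusted p = 0.0082, and adjusted p = 0.55 with an estimated correlation), and 4 were called over the list alone. None of the 3 was called without contra_24h replicate 1 (edgeR adjusted p from 0.144 to 0.181) or ipsi_24h replicate 1 (0.174 to 0.262), and miR-181c-5p was not without contra_24h replicate 2 (0.129), ipsi_24h replicate 2 (0.090) or ipsi_24h replicate 3 (0.068). In the miR-30 family 1 of 5 fell, with a median of -0.74 (adjusted p = 0.0076, and adjusted p = 0.55 with an estimated correlation), and 4 were called over the list alone. That 1 call, miR-30c-5p, was lost without replicate 1 or 2 of contra_24h (edgeR adjusted p = 0.0503 and 0.213) or of ipsi_24h (0.255 and 0.091). In the Dlk1-Dio3 imprinted cluster, which is expressed in brain, 42 of 48 members had values below 0 and none was called lower, with a median of -0.42 (adjusted p = 4.4e-04, and adjusted p = 0.55 with an estimated correlation). Its 2 called members rose: miR-494-3p by a log2 fold change of 5.10 ± 0.73 and miR-665-3p by 1.44 ± 0.44. Against the 286 abundant miRNAs alone, a camera test chosen after the data were seen, none of the 4 passed: the adjusted p was 0.074 for let-7 (median 0.28 below theirs on the log2 scale), 0.46 for miR-181 and for miR-30, and 0.51 for the 31 abundant members of the Dlk1-Dio3 cluster, whose median lay 0.02 above theirs. Under total counts the let-7 and miR-30 medians were -0.25, that of miR-181 -0.23, and that of the Dlk1-Dio3 cluster turned to 0.08. With the replicate block 9 members of the Dlk1-Dio3 cluster were called lower and 3 higher, and 4 of the miR-30 family were lower. miR-665-3p was not called without ipsi_24h replicate 1 (edgeR adjusted p = 0.40), contra_24h replicate 1 (0.125) or contra_24h replicate 3 (0.097). Without contra_24h replicate 1 the number of lists was 7.

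The other lists did not pass camera at 24 h. The cluster of miR-132 and miR-212, regulated by neuronal activity, had a median log2 fold change of -0.59 (camera adjusted p = 0.067, and 0.020 with the replicate block), the neuron-enriched list -0.49 (0.075, and 0.026 with the block), the miR-23/27/24 clusters -0.41 (0.073, and 0.026 with the block) and the vascular list -0.61 (0.069, and 0.042 with the block). Without the block each of these 4 had an adjusted p = 0.55 with an estimated correlation. The medians were -0.53 for the oligodendrocyte-enriched list (0.17), -0.36 for the erythrocyte list (0.24), -0.12 for leukocyte and microglia (0.43), -0.48 for choroid plexus (0.43), -0.55 for the miR-15/16 family (0.17) and -0.14 for miR-210 (0.51). No member of any of these lists was called. With the block 3 members each of the miR-132 and miR-212 cluster and of the miR-23/27/24 clusters were called lower, and calls that the block added in other lists are not all named here. Over the list alone 1 member of the miR-132 and miR-212 cluster was called. Under total counts the medians lay above 0 for miR-23/27/24 (0.08), erythrocyte (0.14), leukocyte and microglia (0.32), choroid plexus (0.02) and miR-210 (0.38). In the miR-17/92 clusters 2 of 12 members rose, miR-18a-5p by 4.42 ± 0.92 and miR-18b-5p by 2.86 ± 0.62, while the list's median was -0.23, its mean 0.37 and its test directed down (adjusted p = 0.51). In the miR-34 family, regulated by p53, 1 of 5 rose, miR-34c-3p by 1.17 ± 0.37 (list median -0.43, adjusted p = 0.51). The call of miR-34c-3p was lost without contra_24h replicate 1 (edgeR adjusted p = 0.070) or 3 (0.16), or ipsi_24h replicate 1 (0.28) or 2 (0.069). Under total counts the medians of the miR-34 family and miR-17/92 were 0.04 and 0.27. For the miR-200 and miR-183 clusters the median was -0.11, the mean 0.17 and the test directed down (0.76), with a median of 0.38 under total counts. For meninges and fibroblast they were 0.03 and -0.08, also directed down (0.61), with a median of 0.55 under total counts. The muscle list's tested member, miR-133a-3p, had -0.83 ± 0.33 (edgeR adjusted p = 0.11, and 0.014 with the block). The inflammation-responsive list had a median of 0.38 (0.75). Its member miR-21a-5p, a miRNA raised in many injured tissues, had 0.38 ± 0.27 (edgeR adjusted p = 0.40) under TMM and 0.89 (adjusted p = 0.0091) under total counts.

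The miR-29 family, whose members are abundant in adult brain, was a list fixed beforehand, and none of its 3 members was called between the hemispheres at any time. At 24 h miR-29a-3p was at 8711 ± 1451 CPM in ipsilateral and 12918 ± 4143 CPM in contralateral cortex (SD, n = 3), a log2 fold change of -0.57 ± 0.39 (SE, edgeR adjusted p = 0.39). miR-29b-3p had -0.59 ± 0.41 (adjusted p = 0.40) and miR-29c-3p -0.60 ± 0.37 (adjusted p = 0.34). With the replicate block miR-29a-3p and miR-29c-3p were called (edgeR adjusted p = 0.047 and 0.041) and miR-29b-3p was not (0.16). Under total counts the 24 h values were -0.07, -0.08 and -0.10. The log2 fold changes of miR-29a-3p, miR-29b-3p and miR-29c-3p were -0.31, -0.24 and -0.37 at 3 h, -0.56, -0.42 and -0.45 at 6 h, and -0.05 (0.07 under total counts), 0.12 and 0.04 at 12 h. As a list the family had camera adjusted p values of 0.30, 0.053, 0.93 and 0.17 at 3, 6, 12 and 24 h, and 0.014 at 6 h with the replicate block (adjusted p = 0.58 with an estimated correlation and no block). In sham cortex miR-29a-3p was at 12035 ± 3277, miR-29b-3p at 248 ± 51.6 and miR-29c-3p at 1407 ± 328 CPM. Against sham, miR-29c-3p at 24 h had -0.63 ± 0.37 (edgeR adjusted p = 0.32, and 0.035 with the block). The hairpins of miR-29a and miR-29b-1 lie on chromosome 6, at 31062660 to 31062747 and 31063023 to 31063093, and those of miR-29b-2 and miR-29c on chromosome 1 in exons of A330023F24Rik (GRCm38).

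**Figure D3:**
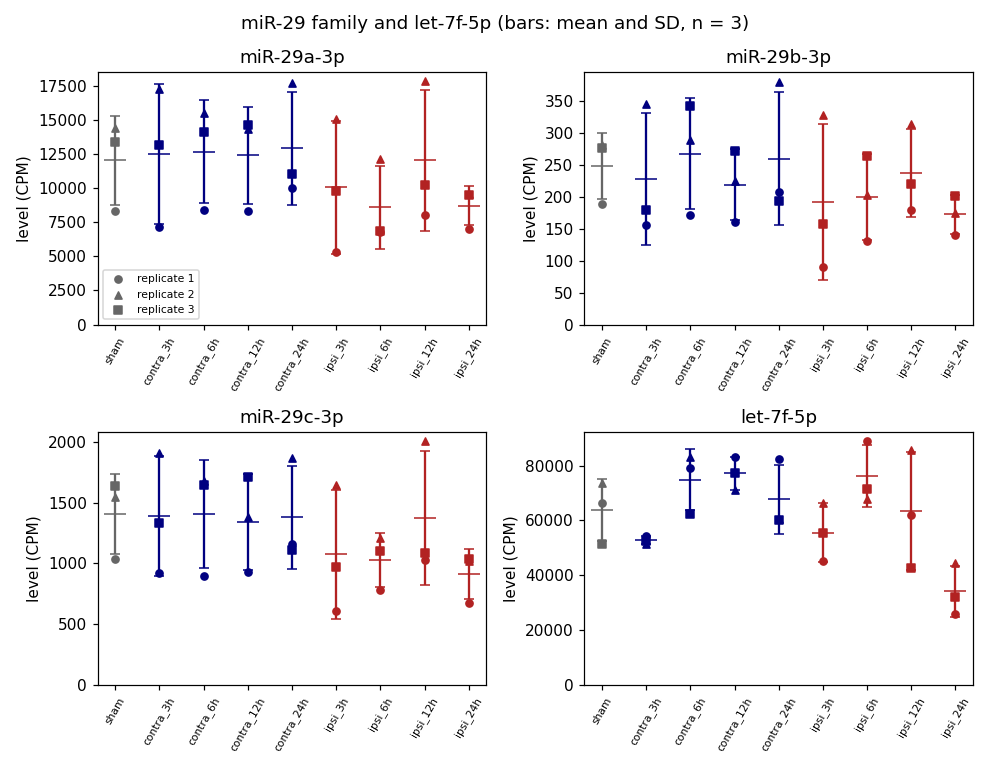
Levels in CPM of miR-29a-3p, miR-29b-3p, miR-29c-3p and let-7f-5p in each library, with group means and SD (n = 3) and marker shapes for the replicate. At 24 h the ipsilateral mean of miR-29a-3p was 8711 CPM and the contralateral 12918 CPM, and for let-7f-5p they were 34113 and 67689 CPM.

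The comparisons with sham ask whether each hemisphere differed from cortex of animals without occlusion. The contralateral cortex gave no call at 3, 6, 12 or 24 h by edgeR or DESeq2. An unadjusted edgeR p under 0.05 was reached by 26, 34, 64 and 33 entries, where 73.5 would be expected by chance. Neither the lack of calls nor the counts under 73.5 show that contralateral and sham cortex are equal. Without sham replicate 1 there was 1 call at 12 h and 1 at 24 h, and without contra_12h replicate 1 there was 1 at 12 h. Ipsilateral cortex gave no edgeR call at 3 and 6 h, with 86 and 54 entries at an unadjusted p under 0.05, against the same 73.5 by chance. DESeq2 called 18 and 4, and the replicate block 1 at each time. Without ipsi_3h replicate 2 edgeR called 3 at 3 h. At 12 h, 70 were higher and 10 lower than in sham, and at 24 h 166 were higher and 20 lower (edgeR). With the replicate block 58 were higher and 8 lower at 12 h, and 207 higher and 69 lower at 24 h. At 24 h miR-701-5p had a log2 fold change of 8.43 ± 0.90 over sham (SE), miR-7687-3p 7.08 ± 1.00, miR-718 6.28 ± 0.84, miR-1893 6.11 ± 0.89, miR-6968-5p 6.01 ± 0.79 and miR-7040-5p 5.56 ± 0.89. At 12 h the leading entries were miR-701-5p with 6.41 ± 0.83, miR-7687-3p with 5.71 ± 0.95, miR-1893 with 4.78 ± 0.84, miR-718 with 4.76 ± 0.79, miR-6968-5p with 4.56 ± 0.74 and miR-2861 with 4.42 ± 0.79. Without ipsi_12h replicate 3 the edgeR adjusted p at 12 h was 0.051 for miR-1893 and 0.055 for miR-2861. Under total counts the calls were 35 higher and 1 lower at 12 h and 194 higher and 4 lower at 24 h.

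Among the calls lower than sham, the largest were members of the miR-200 and miR-183 clusters. At 24 h miR-182-5p had a log2 fold change of -5.82 ± 1.83 (SE, edgeR adjusted p = 0.040), miR-141-3p -5.06 ± 1.34, miR-200a-3p -4.91 ± 1.43, miR-429-3p -4.46 ± 1.17 and miR-200b-3p -2.94 ± 0.89. miR-100-3p had -1.27 ± 0.40. At 12 h miR-141-3p had -5.38 ± 1.38 and miR-429-3p -3.86 ± 1.14, and miR-693-3p -1.33 ± 0.32 and miR-7026-3p -1.31 ± 0.38 were the other named entries. The call of miR-7026-3p was lost without any 1 of the 6 libraries (edgeR adjusted p from 0.061 to 0.185), and that of miR-693-3p without sham replicate 2 (0.064) or ipsi_12h replicate 3 (0.123). These cluster values rest on sham replicate 2, in which miR-182-5p was at 22414 CPM, against 143 and 87.9 CPM in the other sham libraries. Without that library the log2 fold change of miR-182-5p at 24 h was 0.21, and the edgeR adjusted p at 24 h was 0.93 for miR-141-3p, 0.79 for miR-200a-3p, 0.80 for miR-429-3p and 0.71 for miR-200b-3p. At 12 h it was 0.93 for miR-141-3p and 1.00 for miR-429-3p without sham replicate 2, and without ipsi_12h replicates 1, 2 and 3 it was 0.086, 0.084 and 0.26 for miR-141-3p and 0.149, 0.123 and 0.448 for miR-429-3p. Each ipsi_24h library also ended calls when left out: without replicate 1 the adjusted p of miR-182-5p was 0.19, without replicate 2 0.13 and without replicate 3 0.11. For the other cluster members named at 24 h it lay between 0.055 and 0.188 where the call was lost. For miR-100-3p it was 0.23 and 0.059 without ipsi_24h replicates 1 and 2, and 0.066 and 0.114 without sham replicates 1 and 2. With the replicate block miR-429-3p at 24 h was called (edgeR adjusted p = 0.039), and miR-141-3p, miR-182-5p, miR-200a-3p and miR-200b-3p were not (0.059, 0.074, 0.067 and 0.064). At 12 h neither miR-141-3p (0.12), miR-429-3p (0.175) nor miR-7026-3p (0.053) was called with the block. Without sham replicate 2 the counts were 24 at 12 h and 121 at 24 h, with 2 lower calls at each time, and without it and ipsi_6h replicate 3 they were 27 and 123. The 12 h count was 40 without sham replicate 3, 7 without ipsi_12h replicate 3 and 0 in a fit of the 6 libraries alone, and the 24 h count was 92 without ipsi_24h replicate 1. The 10 lower calls at 12 h became 6 without sham replicate 3, 5 without ipsi_12h replicate 1 or 2 and 0 without ipsi_12h replicate 3, and the 20 at 24 h became 1 without ipsi_24h replicate 1 and 11 without ipsi_24h replicate 2. With RLE factors and by DESeq2 the lower calls at 12 h numbered 5 each, and at 24 h 17 and 23.

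**Figure D4:**
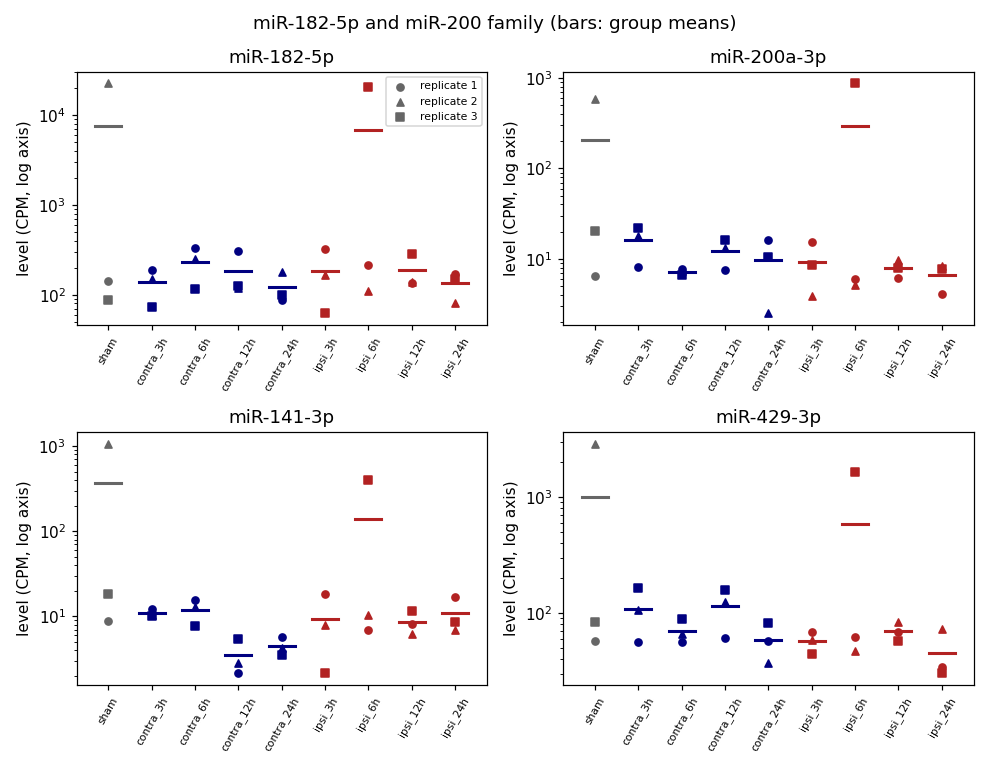
Levels in CPM on a log axis of miR-182-5p, miR-200a-3p, miR-141-3p and miR-429-3p in each library, by group, with bars at the group means and marker shapes for the replicate. Sham replicate 2 and ipsi_6h replicate 3 stand above all other libraries, with miR-182-5p at 22414 and 20224 CPM.

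Over the 4 times together, the hemispheres differed at some time for 132 miRNAs (edgeR joint F test), and for 64 without replicate 1 and 80 without replicate 2 of every group. The difference itself changed over time for 9 miRNAs, all with larger values at 24 h than at 3 h. miR-701-5p had the smallest adjusted p, 0.017, and its log2 difference between the hemispheres was larger by 6.16 ± 1.05 (SE) at 24 h than at 3 h. miR-3109-5p, miR-5627-3p, miR-718, miR-494-3p, miR-7666-5p, miR-6240, miR-7237-3p and miR-1247-5p were the other 8. None of the 9 passed with the replicate block, where the smallest adjusted p of these was 0.091. The count was 0 without replicate 1 or replicate 2, 59 without replicate 3, and 46 by DESeq2.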

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

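The draws that regroup libraries and the test of GC content were set before their results were seen, and the tests of the common shift and of the opposite arms were chosen after the result was seen. The difference between the hemispheres was larger at 24 h than at 3 h for 12 miRNAs by a direct test, and it changed over the 4 times for 9 miRNAs by the joint test (edgeR, adjusted p under 0.05). The log2 differences between 24 h and 3 h were 6.16 for miR-701-5p, 5.52 for miR-3109-5p, 4.70 for miR-5627-3p, 4.63 for miR-718, 4.50 for miR-494-3p, 4.40 for miR-7666-5p, 4.04 for miR-6240, 3.30 for miR-7237-3p and 3.12 for miR-1247-5p. The direct test did not pass for miR-6240 (edgeR adjusted p = 0.058). When times were permuted within surgery days, 10 of 100 draws, the real one included, gave 9 or more calls, and the highest of the others gave 114, so chance is not excluded for this count. Why a draw can give 114 calls, far above the real count, was not tested. In replicate 3 miR-701-5p was higher in ipsi_12h than in ipsi_24h (3952 against 2343 CPM of the totals), and in replicates 1 and 2 it was lower. In the fit with the replicate block no change over time was called.

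These entries belong to the wider rise of 174 entries in ipsilateral over contralateral cortex at 24 h. After each library's trend of level on hairpin GC content was removed, 157 entries were called higher in the fit with the replicate block. Before the removal it was 193 of the same 1438 entries. Called lower were 183, against 95 before. The median log2 fold change of the entries called in the main test went from 2.71 (quartiles 1.93 and 3.79) to 2.17 (1.43 and 3.04). That of the rest went from -0.03 to -0.30. The fitted trend also held each library's mean deviation, so these changes mix a change of scaling with GC content. The GC content of the whole hairpin, as tested, therefore does not account for the whole rise. That of the reads themselves was not tested. A shift shared by all entries does not account for it either: TMM brings the median of all entries to 0.08 and still left 174 calls, against 226 under total counts. TMM does not remove a rise of rare entries relative to abundant ones, so that stays open. Of the 174, 142 had means under 100 CPM over all libraries and 32 did not. If the hairpins were made more, both arms should rise. For the 21 called arms whose opposite arm had at least 20 CPM in contralateral cortex, the called arms had a median log2 fold change of 2.58. Their opposite arms had -0.0027 (quartiles -0.44 and 0.37), and 3 of them, from 2 hairpins, were also called higher. So these opposite arms did not rise as a set. That does not decide on transcription, because the called arms were picked for their rise in these same data. The floor on the opposite arm's level also kept mostly pairs in which that arm was the more abundant one. For the other 153 called entries this cannot be told either, because the opposite arm was rare, not tested or not named. Since the table holds no read sequences, fragments of other RNAs that match these entries remain possible. They are an untested explanation beside higher transcription or an effect of the occlusion on how these RNAs are cut or kept.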

How the results depend on the processing

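All alternatives were planned before the data were examined except TMM factors from abundant miRNAs, camera against abundant miRNAs and the fit without the 2 libraries of high miR-182-5p. Where no cause is given, the cause was not tested. The counts of contralateral cortex against sham stayed at 0 in every alternative other than leaving out 1 library. For ipsilateral against contralateral cortex at 3 h, with 0 calls in the main test, RLE factors gave 1, no filter 1, DESeq2 11 and the 6 libraries alone 11, and DESeq2 gave 4 at 6 h. At 12 h, with 64, TMM of abundant miRNAs gave 39 and the 6 libraries alone 0, a fit with fewer samples. At 24 h, with 195, the replicate block gave 294. For ipsilateral cortex against sham at 3 h, with 0, RLE factors, no filter, the replicate block and thinning each gave 1, DESeq2 18 and the 6 libraries alone 15. At 6 h, with 0, the replicate block gave 1 and DESeq2 4. At 12 h, with 80, total counts gave 36, TMM of abundant miRNAs 37, the fit without the 2 libraries 27 and the 6 libraries alone 0, and at 24 h, with 186, the fit without the 2 libraries gave 123. The change over time, with 9 calls, had 0 under total counts, the replicate block and TMM of abundant miRNAs, 1 after thinning, 5 without the 2 libraries and 46 by DESeq2. The number of lists passing at 3 h, 0 in the main test, was 3 with the replicate block and 2 with TMM of abundant miRNAs. At 6 h, with 5 lists, it was 9 under total counts, the replicate block and TMM of abundant miRNAs, 2 without the 2 libraries, and 0 with an estimated correlation, with camera against abundant miRNAs and with fry. At 24 h, with 4 lists, it was 8 with the replicate block, 7 with TMM of abundant miRNAs, 0 with an estimated correlation and with camera against abundant miRNAs, and 2 with fry. Leaving out 1 library gave 0 to 2 calls for ipsilateral against contralateral cortex at 3 h, 0 to 1 at 6 h, 10 to 104 at 12 h and 107 to 225 at 24 h. Against sham it gave 0 to 3 at 3 h, 7 to 108 at 12 h and 92 to 2.1e+02 at 24 h for ipsilateral cortex, and 0 to 1 at 12 h and at 24 h for contralateral cortex. For lists it gave 0 to 8 at 3 h, 1 to 10 at 6 h, 0 to 2 at 12 h and 4 to 7 at 24 h. Leaving out a replicate of every group gave 64 to 119 calls at any time and 0 to 59 for the change over time. The log2 fold change of miR-182-5p in ipsi_24h against sham, -5.82, ranged from -6.51 to 0.21 when 1 library was left out, was 0.21 without sham replicate 2, and turned to 0.21 without the 2 libraries, since of the 6 libraries compared sham replicate 2 alone held a high level. The overlap of the 12 h and 24 h calls, 64 entries, was 54 with the replicate block and 73 at a threshold of 0.1. For single miRNAs a reversal was counted only where either value passed the threshold. Of the named miRNAs' calls in the pairwise comparisons the replicate block ended 8, all given beside their results. It added 36, of which 35 are at 24 h between the hemispheres, and not all of these are named beside a result. The block also ended all 9 calls of the change over time. The fit of only the 6 libraries ended 47 of the named pairwise calls, total counts 26, TMM of abundant miRNAs 23 and no filter 18. DESeq2 ended 5, RLE factors 4 and thinning 2. Under the block the other totals of calls and numbers of lists stayed within 1.5 times of the main value, with the calls lower than sham at 24 h going from 20 to 69. Counts of a few reads may limit the rare entries, since the median entry of a library had between 6 and 29 counts. The self-test at 24 h recovered 23% of 2-fold changes over entries of all levels, and it was not split by level.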

Other observations

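The tests of the scaling, of let-7 against abundant miRNAs and of the 2 libraries with high miR-182-5p were chosen after the results were seen, and the regroupings of the libraries were planned. At 24 h miR-34c-3p had a log2 fold change of 1.17 ± 0.37 (SE, edgeR adjusted p = 0.033), a call lost without contra_24h replicate 1 (0.070) or 3 (0.16) or ipsi_24h replicate 1 (0.28) or 2 (0.069). miR-34c-5p, the more abundant arm, was at 214 ± 3.44 CPM in ipsilateral and 430 ± 187 CPM in contralateral cortex (SD, n = 3, edgeR adjusted p = 0.13, and 0.045 with the replicate block). The difference between the 2 arms was not tested. Of the 174 entries called higher, 101 had a tested opposite arm, and 14 of these opposite arms were called higher too, which are both arms of 7 hairpins. In the Dlk1-Dio3 cluster miR-494-3p rose in ipsilateral cortex from 8.04 ± 2.03 to 279 ± 248 CPM (SD, n = 3), with 542, 243 and 51.0 CPM in the 3 replicates.

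The fall of abundant miRNAs at 24 h may follow from the scaling. The ipsi_24h libraries had a mean TMM factor of 1.29 ± 0.13 (SD, n = 3), against 0.92 ± 0.08 in contra_24h, and the entries whose mean lies below the median mean took 0.85% ± 0.23 of their counts, against 0.50% ± 0.10. With TMM factors from abundant miRNAs the number called lower went from 21 to 4, and under total counts to 0. Because 20 of the 21 are abundant miRNAs, which those factors centre, that outcome follows from the factors, so the scaling and a real fall of abundant miRNAs cannot be told apart. Also open is whether let-7 fell beyond the other abundant miRNAs: its median lay 0.28 below theirs on the log2 scale, and camera against the 286 abundant miRNAs gave an adjusted p of 0.074, which does not decide it.

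In sham replicate 2 and ipsi_6h replicate 3, 7 of the 1842 entries were both at 10 CPM of the totals or more and above 2 times the highest of the other 25 libraries. Rarer entries were not counted. All 7 belong to the 8 members of the list of miR-200 and miR-183 clusters fixed before the data were examined. Among the 6 tested members it held for 5, and among 149 tested members of the other lists for 0. miR-182-5p was at 18878 and 20875 CPM of the totals in these 2 libraries and at most at 492 CPM in the others. The other 4 replicates of these groups reached at most 227 CPM, so the high level was not shared by either group. Because the 2 libraries were picked for this level, that is no separate test of an effect of the sham operation or of 6 h of recovery. A piece of neighbouring tissue rich in these miRNAs in the 2 dissections stays open. The count of 5 includes miR-182-5p, for which the libraries were picked, and was chosen after the levels were seen. No level of any tissue was compared.

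With 10 splits of 6 libraries no share under 0.05 can occur, so the pairwise comparisons are given as values only. The real split gave 195 calls for ipsilateral against contralateral cortex at 24 h and the highest other split 1, and at 12 h the values were 64 and 0, with 1 split as high as the real one, the real one itself. Against sham the values for ipsilateral cortex were 186 and 1 at 24 h and 80 and 0 at 12 h. The comparisons with 0 calls had 10 of 10 splits as high, with a highest other split of 6 for ipsilateral cortex against sham at 6 h, 1 for contralateral cortex against sham at 12 h and 0 for the rest. Of the 10 splits, 4 part all 3 pairs of the same surgery day, the real one included, and the remaining 6 put both libraries of a day on one side. Among the 4, the highest other value was 0 for all of these comparisons except ipsilateral cortex against sham at 6 h, where it was 6. For the lists, 10 of 10 splits were as high at 3 h (0 lists, highest other 14), 3 at 6 h (5 lists, highest other 10), 10 at 12 h (0 lists, highest other 11) and 5 at 24 h (4 lists, highest other 6). Among the 4 splits that part all pairs the highest other values were 1, 2, 4 and 6. The split with 14 lists at 3 h, where the real one had 0, put both libraries of a day on one side. Why it gave so many lists was not tested. When hemispheres were swapped at random within time and surgery day, 4 of 100 draws, the real one included, gave 132 or more miRNAs that differed at any time. The highest other draw gave 141, and a further one gave 131. The joint F test ignores the direction of a difference. A draw that swaps all 3 pairs of a time, or none, keeps the real grouping at that time. Such draws hold the real difference, so a share near 0.05 can arise without chance. The draws therefore do not decide on chance for this count.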
